A study of Mus musculus with 10 samples.

How the data were processed

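RNA was sequenced from primary keratinocytes, the main cell type of the epidermis, grown from the skin of mouse pups at postnatal days 4 to 5. Per the labels, pups carried 2 mutant copies of Bcl10 (knockout) or 1 mutant and 1 normal copy (heterozygous littermates), on the allele Bcl10tm1Mak. BCL10 is an adaptor protein that joins CARD-family proteins to MALT1 in NF-kB signalling. Per the labels' protocols, cells grew on collagen in serum-free keratinocyte medium with 0.05 mM calcium chloride and received 200 ng/mL recombinant mouse IL-17A for 5 h or no stimulation. Libraries were made from 100 ng of total RNA after poly(A) selection, with a kit of the NEBNext Ultra II series, per the labels' protocols. The part of Bcl10 that the mutant allele removes is not given in the sources used here.

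The authors deposited 1 table of FPKM values for 37991 Ensembl gene identifiers in 10 libraries. Per the submitters' processing notes, the tools were HISAT2, SAMtools, StringTie and DESeq2 and the genome build was mm10; versions, the step that each tool performed, the strand setting and the annotation release are not given in the sources used here. Of the identifiers, 32919 were matched to a symbol and a GRCm38 position (the assembly behind mm10), and 17074 stood at 0 in every library. FPKM values are not counts, so no count model was run. Values of gene models that overlap or have near-identical copies, such as the Sprr2 family, are uncertain, because the sharing of reads between them was not given. An exact 0 or a very low value can be a failed estimate: Gapdh, a glycolytic enzyme gene used by every cell, was listed at 0.278 to 4.58 FPKM.

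The depth of each library is not in the table and was estimated from the steps of low values. In single-exon genes of 300 to 3000 bp, 47.6% to 52.4% of values of 1 to 3 steps lay within 0.05 of a whole number of fragments, where evenly spread values would give 10%. These steps correspond to 15.8 to 50 M fragments per library, and 3 fragments in a gene of 1 kb then equal 0.0600 to 0.189 FPKM. Genes at 1 FPKM or more numbered 11889 to 12092 per library. These floors cover counting error only.

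Groups were taken from the labels: 2 unstimulated and 2 IL-17A-treated libraries labelled knockout, and 3 and 3 labelled heterozygous. Libraries with the same genotype and number are called a culture here. The labels do not say whether the numbers stand for separate animals, litters or wells, so p-values measure the spread between these libraries, which may be partly technical. The pairing of numbers was checked before the fits were compared. The deviations from the group means of same-numbered libraries correlated across genes at 0.227 in the knockout cultures (a single value, since 2 cultures mirror each other), and at 0.607, 0.488 and 0.137 in heterozygous cultures 1, 2 and 3. Numbers were therefore taken to pair libraries within a genotype. The main fit below does not use this pairing, which enters only the fits with culture as a block and the averaged effect. In the main fit, differences between cultures stay in the spread for IL-17A. Between genotypes, the libraries of a culture count as independent there. Across genotypes the same numbers gave -0.155, -0.113, 0.0476 and -0.0401, and were not taken as pairs.

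Genes with a mean of at least 1 FPKM over the 10 libraries (12054 genes) were tested on log2(FPKM + 1) with limma and its mean-variance trend, in 1 fit with a mean for each of the 4 groups. The comparisons were IL-17A against no stimulation in each genotype, knockout against heterozygous in each condition, and the difference between the genotypes' IL-17A responses. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all tested genes, and the threshold was an adjusted p of 0.05. A log2 change on this scale understates the change of genes near or below 1 FPKM, and every fold given is on the log2(FPKM + 1) scale. If no gene changed, about 603 of 12054 genes would lie under an unadjusted p of 0.05 (683 of 13656 with TPM scaling). The main fit had 162 for IL-17A in the libraries labelled heterozygous, 176 in those labelled knockout and 143 for the difference in response. With culture as a fixed block these counts were 835, 607 and 624. Counts near the expected number give no sign of further changed genes. Those of the main fit lie far below it, so its p-values may run too large. The main fit leaves differences between cultures in the spread for IL-17A. Its low counts therefore do not show that no further genes changed.

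There were 28 gene lists. They covered chemokines, antimicrobial and acute-phase proteins, cytokines and growth factors, NF-kB and IL-17 target regulators, proximal IL-17 receptor signalling, the CARD-BCL10-MALT1 complex with MALT1 substrates, basal keratinocytes, terminal differentiation, wound and stress genes, cell cycle, interferon-stimulated genes, antigen presentation, immediate early and AP-1 genes, NRF2 targets, sterol biosynthesis, hypoxia and glycolysis, sex-linked genes, and markers of fibroblasts, melanocytes, myeloid cells, T cells, mast cells, endothelium, hair follicle and sebaceous gland, muscle, nerve, adipocytes and erythroid cells. The 18 lists with at least 5 tested genes were compared with the other genes by limma's camera with a preset correlation of 0.01, adjusted over 90 tests. The same tests were repeated with an estimated correlation and with fry. Of 31 calls with the preset correlation, 0 held with an estimated correlation and fry called 0 lists in 1 direction, with 5 called for changes in either direction. Each call of a list in the text therefore rests on the preset correlation.

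Genes were named by a rule. It took Bcl10 and Malt1, and in each comparison up to 12 genes with the highest and 12 with the lowest log2 change among those past the threshold whose groups did not overlap. Where fewer than 5 passed, the 5 with the smallest unadjusted p were added as not passing. It also took up to 4 members of each list by unadjusted p, and skipped predicted gene models. Genes named outside it are said to have been chosen after their values were seen. The groups, tests, lists, naming rule and the first set of alternative settings were chosen before the data were examined. Added afterwards were the IL-17A effect averaged over the 5 cultures with culture as a fixed effect, the libraries numbered 14 or less alone and their list tests with an estimated correlation, the list tests with an estimated correlation and the culture block, a count of fibroblast genes above the depth floor, protein-coding genes alone, naming of genes without heterozygous culture 1, and the fit that combined that omission with the culture block.

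Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios and TPM scaling, limma without the trend, with robust estimation or with library weights, fits of only the groups compared, 3 forms of replicate block, and the omission of each library and each culture. For the 5 comparisons limma stopped the estimation of the library weights before it converged, so a call kept or lost with them says nothing about its stability. The tests were tested on simulated data with 200 changed genes among 12054. Of the genes changed by 1 on the log2 scale, 78% were recovered for IL-17A in heterozygous cells, 70% for IL-17A in knockout cells, 72% and 68% for the genotypes without and with IL-17A, 38% for the difference in response and 91% for the averaged effect. At a change of 2 these shares were 94%, 92%, 93%, 94%, 88% and 95%. Of the unchanged genes 3, 14, 8, 7, 6 and 14 were called in the same order. The simulated libraries varied independently of each other, with no difference between cultures or sets of library numbers. These shares and counts therefore need not hold for the real libraries, which have such differences. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.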

Results

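The transcriptomes of 10 libraries from 5 keratinocyte cultures were compared to ask how loss of BCL10, an adaptor of the CARD-BCL10-MALT1 complex, alters expression in unstimulated cells and the response to IL-17A, a cytokine that drives antimicrobial and inflammatory genes in the epidermis. There were 2 unstimulated and 2 IL-17A-treated libraries labelled knockout, and 3 of each labelled heterozygous. The estimated depth was 15.8 to 50 M fragments. Krt5, the basal keratinocyte keratin, stood at 4430 to 6426 FPKM in every library.

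Bcl10 (ENSMUSG00000028191; GRCm38 chromosome 3, 145922804 to 145934356, plus strand) checked the genotype labels. In knockout culture 1 it was 0.969 FPKM unstimulated and 16.4 with IL-17A, and in knockout culture 2 it was 17.0 and 16.6. Heterozygous culture 2 had 67.0 and 72.3 FPKM and heterozygous culture 3 had 59.5 and 60.6. The libraries labelled heterozygous culture 1 had 18.0 and 16.3 FPKM, the level of the libraries labelled knockout, which goes against their label. Malt1 (ENSMUSG00000032688; chromosome 18, 65430938 to 65479067, plus strand), the protease partner of BCL10, was 4.62 to 5.26 FPKM in the libraries labelled knockout, 4.67 and 5.04 in heterozygous culture 1, and 2.49 to 2.65 in heterozygous cultures 2 and 3. The 2 libraries of knockout culture 1 differ in Bcl10, and its unstimulated library also stood apart in composition. Its 10 highest genes held 12.6% of all FPKM, against 8.21% to 8.66% in the other libraries. It is 1 of the 2 libraries behind each unstimulated knockout value. The part of the gene model that the mutant allele removes is not given in the sources used here, so a residual level does not by itself contradict a knockout label. The genotype comparisons are therefore given with and without heterozygous culture 1, and every direction between genotypes rests on the labels.

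**Figure D1:**
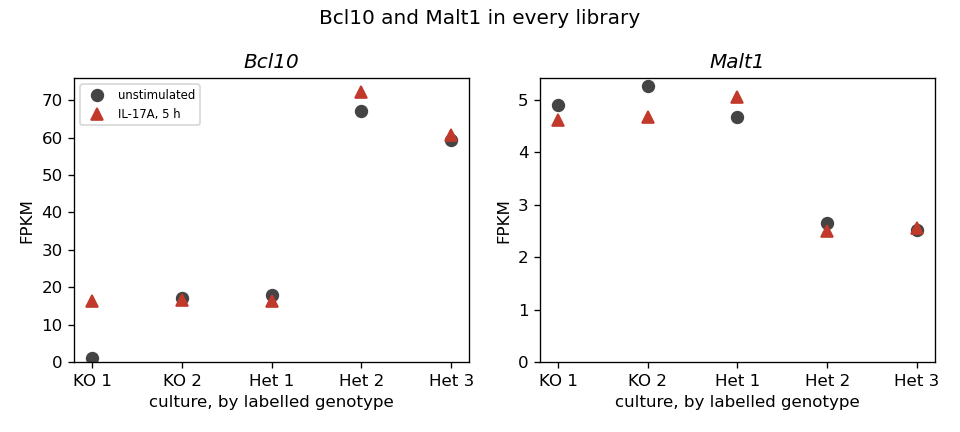
FPKM of Bcl10 and Malt1 (vertical axes) in each library by labelled culture (horizontal axes), with circles for unstimulated and triangles for IL-17A-treated libraries. Bcl10 in the libraries labelled heterozygous culture 1 (18.0 and 16.3 FPKM) sits with the libraries labelled knockout, and below cultures 2 and 3 (59.5 to 72.3 FPKM).

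The same division appeared across the transcriptome and in the labels' library numbers. The first principal component held 40.5% of the variance and placed the libraries labelled knockout and heterozygous culture 1 between -18.1 and -13.5, heterozygous culture 2 at 28.3 and 36.2, and culture 3 at 10.2 and 17.1. Mitochondrial mt-Atp6 was 945 to 1220 FPKM in the first set and 245 to 283 FPKM in the second. All mitochondrially encoded genes together shifted less, from 1.67% to 2.07% of FPKM in the first set to 1.11% to 1.49% in the second. Both cultures labelled knockout and heterozygous culture 1 carry library numbers 1 to 14, and heterozygous cultures 2 and 3 carry 33 to 38. With 0 knockout libraries numbered above 14, genotype and number set cannot be told apart for cultures 2 and 3.

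IL-17A in the libraries labelled heterozygous raised Sprr2e (ENSMUSG00000055030; chromosome 3, 92352143 to 92353449, plus strand), a cornified envelope precursor, from 8.07 ± 1.12 to 21.1 ± 0.961 FPKM (SD, n = 3). This was 2.44-fold (log2 1.29, SE 0.11, adjusted p = 0.0118), in 3 of 3 cultures. It was the only gene past the threshold among 12054, with 1 up and 0 down. Genes with the next smallest p did not pass: Slc5a1, a glucose transporter, log2 1.02 (adjusted p = 0.0928), Sprr2g 0.88 (0.152), the natriuretic peptide gene Nppb 0.69, the calprotectin subunit S100a9 1.06 and the NF-kB cofactor Nfkbiz 0.86 (each 0.298).

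Several gene lists were called upward in these libraries, each with the preset correlation only. Among 19 cytokines and growth factors the median log2 change was 0.34 (camera adjusted p = 6.49e-15, but adjusted p = 0.154 with an estimated correlation). Of these, 0 passed over all genes and 3 rose adjusted over the list alone: the IL-36 receptor antagonist Il1f5 (0.59), the IL-1 receptor antagonist Il1rn (1.14) and the IL-36 gamma gene Il1f9 (0.41). The 7 antimicrobial genes had a median of 0.38 (adjusted p = 5e-13; adjusted p = 0.249 with an estimated correlation), and 2 rose adjusted over the list alone, S100a9 (2.09-fold) and S100a8 (1.90-fold), against 0 over all genes. Of 23 NF-kB and IL-17 target regulators (median 0.12, adjusted p = 1.7e-11; adjusted p = 0.673 with an estimated correlation), 4 rose adjusted over the list alone and 0 over all genes: Nfkbiz (1.81-fold), the ribonuclease gene Zc3h12a (2.36-fold), the transcription factor Cebpd (1.43-fold) and the metalloreductase Steap4 (1.98-fold). The median of this list turned to -0.09 without the unstimulated library of culture 1 (still called upward, adjusted p = 0.0331) and was 0.04 without both libraries of that culture, so the call rests on some of its members. Of 29 wound and stress genes (median 0.09, adjusted p = 9.05e-12; adjusted p = 0.254 with an estimated correlation), Sprr2e and Sprr2g rose adjusted over the list alone (2 genes) and 1 over all genes.

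Other groups in these libraries held few or no single calls. The 9 chemokines had a median of 0.38 (adjusted p = 0.00276; adjusted p = 0.673 with an estimated correlation) with 0 genes adjusted over the list alone and 0 over all genes. The chemokine call was lost without the unstimulated library of culture 1 (adjusted p = 0.183) or the IL-17A library of culture 2 (adjusted p = 0.106). Cell cycle genes (36) had a median of -0.07 (adjusted p = 0.0152; adjusted p = 0.815 with an estimated correlation), also with 0 genes by either adjustment, and lost the call without the same libraries (0.955 and 0.896). Differentiation genes (29) had a median of -0.01 and a mean of 0.04, which differ in sign, at adjusted p = 0.0493 (adjusted p = 0.932 with an estimated correlation), and the call was lost with culture as a block (adjusted p = 0.544). The call was also lost with a pseudocount of 0.1 (0.0551), no filter (0.576), a mean of at least 5 FPKM (0.208), median-of-ratios (0.0803) or TPM scaling (0.397), no trend (0.051), library weights (0.561) and without both libraries of culture 1 (0.496). It was lost without either IL-17A knockout library (0.0688 and 0.0717), the IL-17A library of heterozygous culture 1 (0.182) or the unstimulated libraries of cultures 2 and 3 (0.867 and 0.377). With the block, basal keratinocyte genes were called downward (adjusted p = 0.00103, against 0.217 without it), as they were without both libraries of culture 1 (0.0169). These had adjusted p = 0.732, 0.955 and 0.802 in turn with an estimated correlation. Library weights ended the chemokine (0.0678) and cell cycle (0.873) calls, and the omission of either knockout culture (0.0532 and 0.0576) or of heterozygous culture 2 (0.342) the cell cycle call. The 13 genes of the CARD-BCL10-MALT1 list did not pass as a list (adjusted p = 0.0624), though Zc3h12a, which it shares, rose adjusted over the list alone.

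The Sprr2e call in the libraries labelled heterozygous depended on the fit. Culture as a fixed block left 0 genes by limma (835 at an unadjusted p under 0.05; Sprr2e adjusted p = 0.0545), and culture as a random effect called 15. With only the groups compared, 0 genes passed by limma (141 at an unadjusted p under 0.05; Sprr2e adjusted p = 0.24). Single omissions also ended it: either IL-17A knockout library (adjusted p = 0.0594 and 0.0612 for cultures 1 and 2), the IL-17A heterozygous libraries of cultures 2 and 3 (0.0593 and 0.075) and the unstimulated library of heterozygous culture 3 (0.122), with log2 changes of 1.27 to 1.33. Without both libraries of culture 1, Sprr2e was at log2 1.17 (adjusted p = 0.063) and 0 genes passed by limma (200 at an unadjusted p under 0.05).

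In the libraries labelled knockout IL-17A raised Sprr2e 3.08-fold, from 6.19 ± 0.641 to 21.1 ± 0.324 FPKM (SD, n = 2; log2 1.62, SE 0.13, adjusted p = 0.00944). Lsm12 (ENSMUSG00000020922; chromosome 11, 102162497 to 102185296, minus strand), an RNA-binding protein gene, fell by 1.30 on the log2 scale (SE 0.12, adjusted p = 0.0114), from 30.6 ± 0.719 to 11.8 ± 0.831 FPKM (n = 2). Kbtbd4 (ENSMUSG00000005505; chromosome 2, 90904740 to 90911626, plus strand), a substrate adaptor of a ubiquitin ligase, fell by 0.93 (SE 0.10, adjusted p = 0.0312), from 5.17 ± 0.0467 to 2.25 ± 0.129 FPKM. These 3 genes, 1 up and 2 down, were all that passed. Not passing were the phosphatase Dusp3 (log2 -0.84, adjusted p = 0.0821), the splicing factor Srsf1 (-1.46, 0.161), Sprr2g (1.00, 0.182), the uridine kinase Uck1 (-0.76, 0.199) and Slc5a1 (0.95, 0.28).

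In the libraries labelled knockout, lists were again called upward with the preset correlation only, but the 9 chemokines did not pass (median 0.13, adjusted p = 0.276). Without both libraries of heterozygous culture 1 the chemokine list was called upward (adjusted p = 0.0179; 0.639 with an estimated correlation), with Cxcl1 (log2 0.72) the 1 gene that rose adjusted over the list alone. Of 23 NF-kB and IL-17 target regulators (median 0.13, adjusted p = 3e-07; adjusted p = 0.748 with an estimated correlation), 3 rose adjusted over the list alone and 0 over all genes: Zc3h12a (2.75-fold), Nfkbiz (1.92-fold) and Cebpd (1.76-fold). Of 29 wound and stress genes (median 0.07, adjusted p = 1.66e-10; adjusted p = 0.254 with an estimated correlation), Sprr2e and Sprr2g rose adjusted over the list alone (2 genes), and 1 over all genes. S100a9 (1.77-fold) was the 1 antimicrobial gene of 7 that rose adjusted over the list alone, with 0 over all genes (list median 0.36, adjusted p = 0.000232; adjusted p = 0.53 with an estimated correlation). Lists of differentiation (adjusted p = 0.00275), AP-1 (0.0104) and cytokine genes (0.0152) were called upward and cell cycle genes downward (0.00541), each with 0 genes adjusted over the list alone and 0 over all genes. With an estimated correlation these had adjusted p = 0.795, 0.673, 0.723 and 0.795. The 19 receptor signalling genes were called downward (adjusted p = 0.0482; adjusted p = 0.775 with an estimated correlation) with a median of -0.0033 and a mean of -0.08, so the list did not shift as a whole. Srsf1, a splicing factor, was the 1 gene that fell adjusted over the list alone, with 0 over all genes. The median was above 0 with a mean of at least 5 FPKM (0.01), TPM scaling (0.03) and without the IL-17A library (0.04) or both libraries (0.02) of knockout culture 1, and the call was lost with culture as a block (adjusted p = 0.416). No filter ended the cytokine call (adjusted p = 0.051), and the receptor signalling call was lost with no filter (0.0837), a mean of at least 5 FPKM (0.0839), TPM scaling (0.0539), library weights (0.0678) and only the groups compared (0.199). Without the IL-17A library of knockout culture 2 the antimicrobial (0.315, median -0.03), cytokine (0.869, median -0.0025), differentiation (0.172), AP-1 (0.0537) and receptor signalling (0.172) calls were lost. Without the IL-17A library of knockout culture 1 the cell cycle (0.866, median 0.01), AP-1 (0.325) and receptor signalling (0.249) calls were lost. The unstimulated library of knockout culture 1 ended the cytokine (0.131) and AP-1 (0.0796) calls when left out, and that of knockout culture 2 the cell cycle (0.664), AP-1 (0.0668) and receptor signalling (0.423) calls. The last was also lost without heterozygous unstimulated libraries 1, 2 and 3 (0.0694, 0.0953 and 0.056) and IL-17A library 2 (0.0732).

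Culture as a fixed block left 0 genes by limma in the libraries labelled knockout (607 at an unadjusted p under 0.05; Sprr2e adjusted p = 0.0919, Lsm12 0.0689, Kbtbd4 0.0919), and as a random effect it called 14. Sprr2e and Lsm12 were lost without either library of knockout culture 1 (adjusted p = 0.0569 and 0.0591 for Sprr2e, 0.0796 and 0.0618 for Lsm12), Lsm12 also without the unstimulated library of heterozygous culture 3 (0.0551), and Kbtbd4 without any single library except the IL-17A library of heterozygous culture 1 (adjusted p = 0.0508 to 0.169). The TPM scaling called 1 gene up and 0 down. With only the groups compared, all 3 calls were lost (Sprr2e and Lsm12 adjusted p = 0.0673, Kbtbd4 0.194), and the 3 genes that passed were others, chosen here after their values were seen: Gstp2, Hsp25-ps1 and Gm20656. Leaving out both libraries of knockout culture 1, knockout culture 2 or heterozygous culture 3 also ended all 3 calls (adjusted p = 0.118 to 0.546). Where these calls were lost, the log2 changes were 1.53 to 1.70 for Sprr2e, -1.23 to -1.34 for Lsm12 and -0.88 to -1.05 for Kbtbd4.

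With all 5 cultures in 1 model and culture as a fixed effect, an analysis added after the data had been seen, IL-17A raised 18 genes and lowered 0 (727 at an unadjusted p under 0.05). Each of the 18 is described by its mean change over the 5 cultures. Among them were the cornified envelope genes Sprr2e (log2 1.42, SE 0.09, adjusted p = 0.0064), Sprr2d (1.24), Sprr2i (1.17), Sprr2f (1.07), Sprr2g (0.93) and Lce3b (0.82). The RNA-decay enzyme gene Zc3h12a rose 2.51-fold, the NF-kB cofactor gene Nfkbiz 1.85-fold, S100a8 1.85-fold and S100a9 1.95-fold. The transporter genes Slc6a14 (2.31-fold) and Slc5a1 (log2 1.00) rose as well, as did the granulocyte growth factor Csf3 (1.75-fold). Members of the Sprr2 family have near-identical copies, so their separate values are uncertain. The averaged effect called 6 genes without a filter, 14 with TPM scaling and 16 with a pseudocount of 0.1, so not all of the 18 kept the call there.

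List members in the averaged analysis were more often called. Of 9 chemokines 4 rose adjusted over the list alone and 0 over all genes, the neutrophil attractants Cxcl1 (1.98-fold), Cxcl5 (1.83-fold) and Cxcl2 (1.82-fold) and the T-cell attractant Ccl20 (1.35-fold). Of 7 antimicrobial genes 5 rose adjusted over the list alone and 2 over all genes, among them the protease inhibitor Slpi (log2 0.33) and the defensin Defb14 (0.38). Of 19 cytokines and growth factors 9 rose adjusted over the list alone and 2 over all genes, with Il1f5 at 1.48-fold, Il1f9 at 1.34-fold and Csf2, the granulocyte-macrophage growth factor, at 1.85-fold. Wound and stress genes rose in 10 of 29 adjusted over the list alone and 5 over all genes, and NF-kB and IL-17 target regulators in 6 of 23 and 2. Among 29 differentiation genes 5 rose and 2 fell adjusted over the list alone and 1 rose over all genes. With an estimated correlation these lists had adjusted p = 0.132, 0.0613, 0.172, 0.132, 0.172 and 0.501, in the order given. Cell cycle genes were called downward (adjusted p = 1.15e-07; adjusted p = 0.172 with an estimated correlation). AP-1 genes (0.00103; 0.4 with an estimated correlation) and the CARD-BCL10-MALT1 list (0.00596; 0.501) were called upward and basal genes downward (0.00304; 0.4), with the integrin Itga2 (log2 0.19) up and Itga3 (-0.16) and Col17a1 (-0.15) down adjusted over the list alone.

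**Figure D2:**
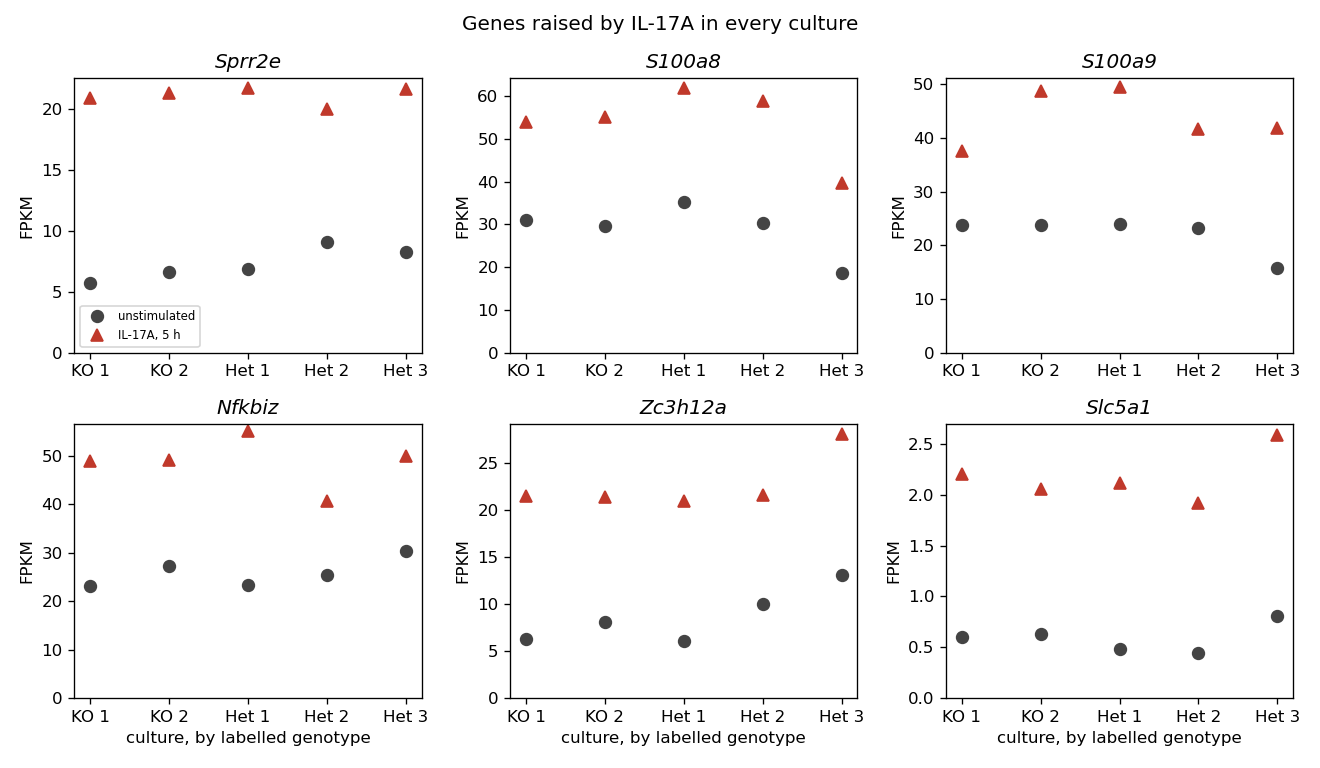
FPKM of 6 IL-17A-responsive genes (vertical axes) in each library by labelled culture (horizontal axes), with circles for unstimulated and triangles for IL-17A-treated libraries. Sprr2e rose from 5.73 to 9.11 FPKM unstimulated to 20 to 21.7 FPKM with IL-17A.

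The count of 18 depended on single cultures, while the changes were upward in each of the 5. By culture the log2 change was 1.05 to 1.70 for Sprr2e, 0.91 to 1.07 for Slc5a1 and 0.61 to 1.46 for Sprr2d. Genes called in this model are favoured for changing alike in all cultures. The count was 0 by limma without knockout culture 2 (499 at an unadjusted p under 0.05), 8 without heterozygous culture 1, 4 without culture 2, 7 without culture 3, 14 without knockout culture 1 and 7 without the block.

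Whether the IL-17A response differed between genotypes was tested as the difference of the 2 changes. By limma 0 genes passed (143 at an unadjusted p under 0.05). Those with the smallest p were Lsm12 (log2 -1.31, adjusted p = 0.105), Uck1 (-1.26, 0.105), Kbtbd4 (-0.99, 0.137), Dusp3 (-0.82, 0.66) and the predicted cytochrome oxidase assembly gene Cox20b (-1.23, 0.804). Over the 18 genes raised by IL-17A over all cultures, the median was log2 0.92 in libraries labelled heterozygous and 0.93 in those labelled knockout, with 10 larger in knockout and 8 in heterozygous. The median ratio was 1.07, and 1.19 without heterozygous culture 1. These genes were picked by the averaged effect, which favours genes that change alike in all cultures, so the values do not show that the responses were equal. Their differences had SEs of 0.17 to 1.16 in the main fit. That fit does not use the pairing, so differences between cultures can widen these SEs. Sprr2f, with the largest SE, changed by log2 1.51 and 1.09 in knockout cultures 1 and 2. In heterozygous cultures 1, 2 and 3 it changed by 0.83, 0.73 and 1.19. For Sprr2e, the 1 gene called in the libraries labelled heterozygous, the knockout change was 1.26 times the heterozygous change on the log2 scale (1.62 against 1.29), a difference of 0.33 (SE 0.17).

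A single list was called for a difference in response, with the preset correlation only. The 19 cytokines and growth factors changed less in the libraries labelled knockout (median difference -0.18, camera adjusted p = 0.0104; adjusted p = 0.673 with an estimated correlation), with 0 genes adjusted over the list alone and 0 over all genes. Il1rn had the smallest p in it (log2 -1.72, SE 0.47): it went from 3.45 ± 0.196 to 2.01 ± 0.69 FPKM in the libraries labelled knockout (n = 2) and from 2.20 ± 1.04 to 6.14 ± 2.37 in those labelled heterozygous (n = 3). The list call was lost without the IL-17A library of knockout culture 1 (adjusted p = 0.325), the unstimulated library of knockout culture 2 (0.133), or the unstimulated libraries of heterozygous cultures 1 (0.106) and 2 (0.0927). It was also lost with no filter (0.132), a mean of at least 5 FPKM (0.0722), library weights (0.169) and without both libraries of knockout culture 1 (0.282) or 2 (0.0827). Without both libraries of heterozygous culture 1 the list median was -0.04 (adjusted p = 0.00474), Il1rn was below the threshold adjusted over the list alone (log2 -2.27, SE 0.25), and 1 gene passed over all genes, Gm20656, a predicted pseudogene chosen here after its values were seen. AP-1 (0.0112) and differentiation genes (0.0283) were then called upward in the difference (adjusted p = 0.561 and 0.639 with an estimated correlation). Srsf1 was the 1 gene of the receptor signalling list below the threshold adjusted over the list alone (log2 -1.20), against 0 over all genes. With culture as a fixed block 0 genes passed by limma (624 at an unadjusted p under 0.05), as a random effect 5 did, and with the fixed block the chemokine list was called downward (adjusted p = 0.00655, against 0.501 without it). Its adjusted p with an estimated correlation was 0.57 with the block and 0.955 without it.

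Between genotypes without stimulation, using all libraries as labelled, 0 genes passed by limma (562 at an unadjusted p under 0.05; smallest adjusted p 0.728). The smallest p belonged to the smooth-muscle actin-binding gene Tagln, at 11.8 ± 0.633 FPKM in the libraries labelled knockout (n = 2) and 4.81 ± 0.991 in those labelled heterozygous (n = 3), log2 1.15. Srsf1 (1.12), Uck1 (0.53), N4bp2l2 (-0.77) and the phosphatase Cdc14b (0.58) followed.

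Gene lists in this comparison went both ways. Lower in the libraries labelled knockout were NF-kB and IL-17 target regulators (median -0.24, adjusted p = 0.00056), chemokines (-0.66, 0.0298), NRF2 targets (-0.16, 0.0104) and melanocyte markers (-0.47, 0.000999). Higher were hypoxia and glycolysis genes (0.17, 0.00202), sterol biosynthesis genes (0.17, 0.00541) and fibroblast markers (1.33, 0.0252). With an estimated correlation these had adjusted p = 0.748, 0.748, 0.524, 0.748, 0.748, 0.795 and 0.775. In the NRF2 list 2 of 16 genes were lower adjusted over the list alone and 0 over all genes, the quinone reductase Nqo1 (log2 -0.72) and the heme oxygenase Hmox1 (-0.53). The other 6 lists had 0 genes by either adjustment. Outside the called lists, Srsf1 and the metalloprotease Mmp10 (0.95) were higher, and the antimicrobial S100a7a (-1.06) and the receptor Kdr (-0.37) lower, adjusted over their lists alone. Omissions ended calls for chemokines (unstimulated libraries of knockout culture 1, 0.322, and heterozygous cultures 2 and 3, 0.0598 and 0.107), hypoxia (knockout culture 1, 0.341), NRF2 (knockout 1, 0.124, and heterozygous 1, 0.295), sterol (knockout 2, 0.0835, and heterozygous 2, 0.121) and melanocyte genes (knockout 2, 0.0508). The fibroblast call was lost without either library of heterozygous culture 1 (0.138 unstimulated, 0.0536 IL-17A). Leaving out both libraries of knockout culture 1 ended the NF-kB call (0.075), and of heterozygous culture 2 the fibroblast call (0.0756). The chemokine call was also lost with no filter (median -0.38, 0.291) and with only the groups compared (0.0544), and library weights ended the NRF2 (0.0931) and fibroblast (0.272) calls.

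Markers of other cells moved with these groups. The pigment enzyme gene Dct was 57.0 to 71.4 FPKM in the libraries labelled knockout, 69.8 and 75.6 in heterozygous culture 1 and 105 to 165 in cultures 2 and 3. Col1a1, the fibroblast collagen gene, was 10.8 and 10.6 FPKM in knockout culture 2 and 0 to 0.186 elsewhere. Among the libraries numbered 14 or less, with 2 labelled knockout against 1 labelled heterozygous, the medians were 0.05 for NF-kB and IL-17 target regulators (adjusted p = 0.228), 0.17 for chemokines (0.66), -0.14 for NRF2 targets (0.0156) and -0.13 for melanocyte markers (0.253). With an estimated correlation their adjusted p were 0.749, 0.824, 0.718 and 0.749, and the lone library was assumed to vary like the other groups. The hypoxia (0.11, adjusted p = 0.217), sterol (-0.06, 0.512) and fibroblast (1.10, 0.169) calls were lost in this set. There, differentiation (median -0.25, adjusted p = 1.87e-06) and AP-1 genes (-0.22, 0.00106) were called lower and interferon-stimulated genes (0.14, 0.00889) higher in the libraries labelled knockout, with adjusted p = 0.657, 0.718 and 0.718 with an estimated correlation.

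With IL-17A, 3 genes were lower in the libraries labelled knockout and 0 higher. Lsm12 stood at 11.8 ± 0.831 FPKM (n = 2) against 28.4 ± 3.07 (n = 3), 2.28-fold lower (log2 -1.19, SE 0.11, adjusted p = 0.0226). Dusp3 (ENSMUSG00000003518; chromosome 11, 101971143 to 101987013, minus strand), a phosphatase of MAP kinases, was 1.96-fold lower (5.11 ± 0.3 against 11 ± 0.898 FPKM, adjusted p = 0.0249) and Kbtbd4 1.83-fold lower (2.25 ± 0.129 against 4.94 ± 0.306 FPKM, adjusted p = 0.0249). Lsm12 and Kbtbd4 also fell with IL-17A in knockout cells, from the same 2 IL-17A libraries. Not passing were Tagln (1.25, adjusted p = 0.194), Uck1 (-0.73, 0.194), and at 0.507 the small nucleolar RNA Snord49a (-1.13), Nppb (-0.67) and N4bp2l2 (-0.85).

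Inflammatory lists were lower in the libraries labelled knockout under IL-17A. Cytokines and growth factors had a median of -0.31 (adjusted p = 0.00056), chemokines -1.17 (0.0102), NF-kB and IL-17 target regulators -0.42 (0.00227) and melanocyte markers -0.46 (0.00197). Higher were hypoxia and glycolysis (0.29, 0.0011), sterol biosynthesis (0.21, 0.0152), basal keratinocyte (0.24, 0.0293) and wound and stress genes (0.03, 0.0493). Each had 0 genes adjusted over the list alone and 0 over all genes. With an estimated correlation these had adjusted p = 0.53, 0.748, 0.775, 0.748, 0.748, 0.815, 0.815 and 0.748. Of the NRF2 targets, which did not pass as a list (0.0512), Hmox1 and Nqo1 (2 genes) were lower adjusted over the list alone and 0 over all genes, and the endothelial Kdr (log2 -0.40) was lower adjusted over its list alone. The IL-17A library of knockout culture 1 ended the chemokine (0.112), hypoxia (0.282) and basal (0.172) calls when left out, and that of knockout culture 2 the melanocyte (0.139), sterol (0.156), basal (0.0733) and wound (0.242) calls. Without the IL-17A library of heterozygous culture 2, sterol (0.311), basal (0.359) and wound (0.245) calls were lost, and the wound call also without the unstimulated libraries of heterozygous cultures 2 and 3 (0.0598 and 0.0501). Leaving out both libraries of knockout culture 1 ended the cytokine (median -0.10, adjusted p = 0.1) and sterol (0.075) calls, and of knockout culture 2 the NF-kB call (0.0571). No filter ended the basal (0.107) and wound (0.0726) calls, library weights the basal (0.0678), wound (0.0953) and sterol (0.297) calls, protein-coding genes alone the basal (0.0583) and wound (0.0838) calls, and a fit without the trend the wound call (0.051). Among the libraries numbered 14 or less, with 2 labelled knockout against the 1 of heterozygous culture 1, the medians were -0.45 for cytokines (adjusted p = 3.06e-08), -0.45 for chemokines (0.0156), -0.14 for NF-kB and IL-17 target regulators (0.037), -0.01 for basal (0.93) and 0.05 for sterol genes (0.93). The melanocyte (-0.05, adjusted p = 0.288), hypoxia (0.21, 0.169) and wound (0.09, 0.769) calls were lost as well. With an estimated correlation the first 3 had adjusted p = 0.718, 0.749 and 0.749, and the lone library was assumed to vary like the other groups. Differentiation (-0.23, adjusted p = 0.000128) and AP-1 genes (-0.23, 0.00552) were also called lower in the libraries labelled knockout in this set (0.657 and 0.718 with an estimated correlation).

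The 3 single-gene calls under IL-17A did not hold with TPM scaling (0 genes by limma, 996 at an unadjusted p under 0.05), with only the groups compared (each at adjusted p = 0.598, where 1 other gene passed, the predicted gene Gm12543, chosen here after its values were seen), with a number shared by genotypes as the block (0.101, 0.101 and 0.104 for Lsm12, Dusp3 and Kbtbd4) or among the libraries numbered 14 or less (adjusted p = 0.124 for Lsm12, 0.348 for Dusp3 and 0.467 for Kbtbd4, where 8 other genes passed). Each was lost without at least 7 of the single libraries; Lsm12 was kept without the IL-17A libraries of knockout culture 2 and heterozygous cultures 1 and 2, and Dusp3 and Kbtbd4 were lost without any 1 library. The changes themselves moved little where the calls were lost: the log2 values were -1.12 to -1.34 for Lsm12 (-1.19 with all libraries), -0.91 to -1.02 for Dusp3 (-0.97) and -0.83 to -0.96 for Kbtbd4 (-0.87).

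Leaving out both libraries of heterozygous culture 1 was among the omissions set beforehand, and naming genes in that fit was decided after Bcl10 had been seen. It gave a different account of the genotypes. Without stimulation 42 genes were higher and 75 lower in the libraries labelled knockout, and with IL-17A 457 were higher and 345 lower. This fit takes the 2 libraries of a culture as independent, although they were taken as pairs above. The spread between 2 and 2 cultures is therefore less well known than its p-values assume. In this fit the granulocyte-macrophage factor Csf2 was 9.30-fold lower without stimulation (0.607 ± 0.0455 against 14.0 ± 2.06 FPKM, n = 2 and 2, adjusted p = 0.00127) and 9.22-fold lower with IL-17A (1.70 ± 0.594 against 23.6 ± 0.612 FPKM, adjusted p = 0.00125). The neutrophil chemokine Cxcl2 was 8.44-fold and 11.4-fold lower, Tnf 4.14-fold and 5.05-fold, and Il23a, a subunit of IL-23, 4.00-fold and 3.40-fold. Heterozygous culture 1, left out here, had 1.15 and 5.31 FPKM of Csf2 and 3.94 and 7.35 FPKM of Tnf.

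By list without heterozygous culture 1, chemokines were lower in 5 of 9 genes over all genes and 5 adjusted over the list alone in each condition. Cytokines and growth factors were lower in 5 of 19 without stimulation and 7 with IL-17A over all genes (8 and 8 adjusted over the list alone), and NF-kB and IL-17 target regulators in 4 and 8 of 24 (12 and 13 adjusted over the list alone), including Tnfaip3, Nfkbia, Relb and Icam1. Both NF-kB lists had adjusted p = 0.489 with an estimated correlation, and the other lists higher values for the genotypes. Differentiation genes were called higher in each condition (adjusted p = 0.0278 and 0.00249; 0.639 and 0.561 with an estimated correlation), against the calls of the same list as lower among the libraries numbered 14 or less (medians -0.25 and -0.23), so the direction called depends on which heterozygous cultures are compared. Basal (0.00808; 0.802) and wound genes (0.0169; 0.659) were called higher without stimulation. The NRF2 (0.6) and fibroblast (0.352) calls without stimulation were lost, while hypoxia, sterol and melanocyte lists kept theirs in both conditions. Higher in the libraries labelled knockout were the smooth-muscle actin Acta2 (6.20-fold without stimulation), Igfbp2 (4.12-fold), Ly6a (4.10-fold), mt-Atp6 (3.97-fold) and fibronectin Fn1 (2.61-fold), and Malt1 (1.70-fold without stimulation and 1.60-fold with IL-17A). The melanocyte gene Pmel was 1.78-fold and 1.87-fold lower. Of the genes called in both conditions, 38 were higher and 71 lower, where independent lists would share 1.59 and 2.15. The conditions are not independent, since they use libraries of the same cultures and 1 estimate of the spread per gene. The excess may come from this, so the overlap is no replication. All of these libraries labelled heterozygous are numbered above 14 and all labelled knockout are not, so genotype and number set cannot be told apart for these genes.

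**Figure D3:**
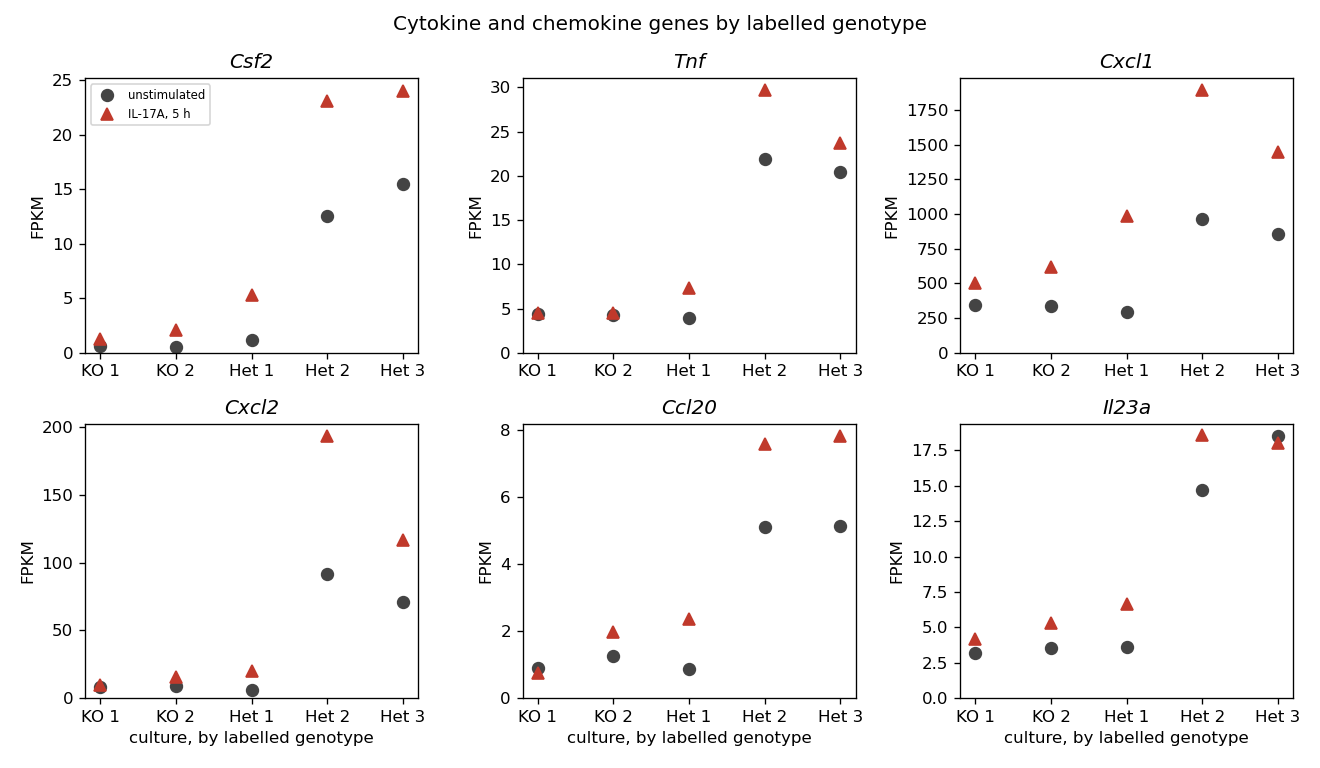
FPKM of 6 cytokine and chemokine genes (vertical axes) in each library by labelled culture (horizontal axes), with circles for unstimulated and triangles for IL-17A-treated libraries. Csf2 was 0.575 to 2.12 FPKM in the libraries labelled knockout, 1.15 and 5.31 in heterozygous culture 1 and 12.6 to 24.0 in cultures 2 and 3.

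The remaining lists gave no call in the 5 comparisons: antigen presentation (9 tested genes), interferon-stimulated genes (9) and the CARD-BCL10-MALT1 complex (13). In all, 10 lists had fewer than 5 tested genes and were not tested as lists. Their highest members averaged 7.79 FPKM for the myeloid gene Cd68, 4.04 for the endothelial Kdr, 60.9 for Plin2 of the sebaceous list, 1.70 for the muscle gene Tnni2, 11.5 for the nerve gene Mbp, 7.69 for the adipocyte gene Lpl and 12.7 for Xist of the sex-linked list. T-cell, mast-cell and erythroid lists held no gene above 0.0642 FPKM on average.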

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

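The list test and the rule below were fixed before the values were seen, except that Il1rn was added to the genes examined after its values had been seen. The rule was applied only to named genes and to list members with an unadjusted p under 0.05 in limma's test of the difference in response. For 5 genes every culture labelled knockout moved one way with IL-17A and every culture labelled heterozygous the other. Kbtbd4, Uck1 and Cox20b had been named for their small p in that difference, so their opposite signs partly follow from the choice. This rule does not test the difference, and in limma's test of it none of the 5 passed over all genes. The log2 change in knockout minus heterozygous was -0.99 for Kbtbd4, -1.26 for Uck1, -0.81 for Snord49a, -1.23 for Cox20b and -1.72 for Il1rn, with falls in both knockout cultures. The change in heterozygous culture 1 was 0.01 for Snord49a and 0.04 for Il1rn, and that of Kbtbd4 in culture 3 was 0.02, so these signs are within the spread. The list of cytokines and growth factors was called in the test of the difference itself with the preset correlation only (camera adjusted p = 0.0104, against 0.673 with an estimated correlation). No group had 4 or more libraries, so no single library was tested against its group.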

How the results depend on the processing

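All alternatives were planned except the averaged effect with its settings, protein-coding genes, the libraries numbered 14 or less and the combined fit without heterozygous culture 1, which were chosen after the results were seen. Across the named genes 869 alternative values stayed on their side of the threshold and in direction, 156 lost the call, 49 gained one and 0 turned; for list calls the counts were 733, 170, 0 and 7. Where a value below moved, the cause was not tested, except that omissions leave fewer libraries. Depth limits genes below about 0.189 FPKM, the level of 3 fragments in a gene of 1 kb in the shallowest library. Values below it were taken only as near 0.

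Main counts were 1 gene for IL-17A in heterozygous cells, 3 in knockout cells, 0 between genotypes unstimulated, 3 under IL-17A, 0 for the difference in response and 18 averaged. For IL-17A in heterozygous cells a pseudocount of 0.1 and TPM scaling each gave 2 genes, and fitting only the groups compared 0. For IL-17A in knockout cells no filter gave 5, TPM scaling 1 and only the groups compared 3, none of them among the 3 main calls. Between genotypes unstimulated, no filter gave 2 and only the groups compared 1; under IL-17A they gave 6 and 1 (with all 3 main calls lost in the latter), and TPM scaling 0. The difference in response had 1 without a filter. Library weights gave 4656, 11, 2929, 3551 and 17 genes for the 5 comparisons and 31 averaged, and put a weight of 33.4 on the IL-17A library of heterozygous culture 3 and 0.197 on that of culture 1. The weights for the 5 comparisons did not converge, so values that rest on them decide nothing; those of the averaged effect did. The averaged count was 6 without a filter, 7 with no replicate block and 28 among protein-coding genes. The libraries numbered 14 or less gave 8 and 8 genes between genotypes.

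With the replicate block, culture as fixed effects gave 0 genes for IL-17A in either genotype, and as a random effect 15, 14 and 5 for IL-17A in heterozygous cells, in knockout cells and for the difference in response. A number shared by genotypes as the block gave 0 for IL-17A in either genotype and 0 between genotypes under IL-17A. The culture block with heterozygous culture 1 left out gave 1 gene in heterozygous and 0 in knockout cells. Beyond the calls given with the results, the culture block ended no list call.

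Leaving out single libraries or cultures gave 0 to 2 genes for IL-17A in heterozygous cells, 0 to 12 in knockout cells, 0 to 117 between genotypes unstimulated, 0 to 802 under IL-17A, 0 to 6 for the difference in response and 0 to 14 averaged; list calls ranged from 14 to 37, against 31, and were 0 with an estimated correlation and 0 by directional fry. The ratio of knockout to heterozygous response, 1.26 with Sprr2e as the only gene, ranged from 0.526 to 1.36 over these omissions, where other genes also entered, was 0.0314 with library weights (4656 genes) and 0.0145 in the combined fit (1 other gene), and turned to -14.0 when the 3 genes called in knockout cells were used. The direction of 7 list tests turned, of which 3 had a median that changed sign; the medians were, for differentiation in heterozygous cells without the IL-17A library of culture 1 (-0.12, against -0.01) or the unstimulated library of culture 2 (-0.07), for cell cycle without the IL-17A library of culture 2 (-0.02), and, among the libraries numbered 14 or less, for chemokines (0.167) and NF-kB regulators (0.0495) unstimulated and basal (-0.00508) and sterol genes (0.0507) under IL-17A. In all, 17 medians of 10 list calls changed sign. With the direction of the test kept, these included sterol genes unstimulated among the libraries numbered 14 or less (-0.0637), and in knockout cells antimicrobial genes without the IL-17A library of culture 2 (-0.0336) and cell cycle without that of culture 1 (0.00577). Without the unstimulated library of heterozygous culture 1, the medians in heterozygous cells were 0.114 for differentiation, -0.0949 for NF-kB regulators and -0.0134 for cell cycle.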

Other observations

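The tests of Bcl10, of the fibroblast genes and of the splits of the heterozygous libraries were chosen after the results were seen; the draw of splits over all 10 libraries was set before its result was seen. Some genes chosen after their values were seen differed between cultures. Ddx3y, encoded on the Y chromosome, was 1.14 to 1.57 FPKM in the libraries labelled knockout, 5.28 and 6.57 in heterozygous culture 1, 0.439 and 0.456 in culture 2 and 0 in culture 3, while Xist, transcribed from the inactive X, was 5.89 to 18.4 FPKM in all libraries. Zfp979, a zinc finger gene, was 0 to 0.0716 FPKM in the libraries labelled knockout and heterozygous culture 1 and 4.54 to 6.16 in heterozygous cultures 2 and 3, and was among the genes called between genotypes without heterozygous culture 1. Small RNA genes stood apart in single libraries, chosen here after their values were seen: Gm23935 was 11549 FPKM in the unstimulated library of knockout culture 1, 2524 in that of heterozygous culture 3 and 196 to 906 elsewhere. Gm17494 was listed at 0 in the unstimulated library of knockout culture 1 and both of heterozygous culture 1, and at 103 to 139 FPKM in the others.

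Bcl10 in the libraries labelled heterozygous culture 1 lay at a position of 0.0289 on the log2 scale between the median of the libraries labelled knockout (0) and that of heterozygous cultures 2 and 3 (1). This argues against the genotype as labelled, but it restates the level that prompted the question and is no separate test. The 3.61-fold difference of Bcl10 between heterozygous culture 1 and cultures 2 and 3 lay at percentile 99.9 of 2847 genes of like level, with 4 larger. For Bcl10 this argues against a number set that acts on genes at random. It cannot exclude a number set that acts on Bcl10 in particular. A wrong genotype label on culture 1 may account for the Bcl10 difference. The first principal component also placed culture 1 with the libraries labelled knockout, so other genes cannot tell a wrong label from the number set. Over 51 chemokine, cytokine and NF-kB genes culture 1 lay on the knockout side, at a least-squares position of 0.169 between the group means. That position gives most weight to the genes that differ most, and either explanation would give it. Under IL-17A, Cxcl1 (985 against 506 and 618 FPKM), Csf2 (5.31 against 1.28 and 2.12) and Tnf (7.35 against 4.45 and 4.46) went the other way. They were higher in culture 1 than in both knockout cultures, as its label would have it. With 0 knockout libraries numbered above 14, the design cannot tell number set and genotype apart for any gene, Bcl10 included. A biological difference of genotype stays open and untested for the other genes.

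Fibroblast genes were highest in knockout culture 2. Of 16 listed fibroblast genes, 16 were higher in both of its libraries than in each other library, 15 of them above the level of 3 fragments in the shallowest library (Mfap5 was below it), among them Col1a1 (10.8 and 10.6 FPKM) and Dcn (7.60 and 8.62 FPKM), which is what fibroblast RNA in that culture would give and may account for the list's call between genotypes. An effect of the knockout genotype is argued against, since 3 of 16 (2 above that level) were higher in both libraries of knockout culture 1 than in each heterozygous library. How many fibroblasts the culture held was not measured.

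Other splits of the same libraries give the counts a scale. Of the 10 splits of the 6 libraries labelled heterozygous into 3 and 3, 4 called at least 1 gene, the real one included (1 gene), and the highest other called 1702; 10 splits are too few for a share under 0.05. That split sets both libraries of culture 1 and the unstimulated library of culture 3 against the rest, which points to a structure of the samples. For the averaged effect, 10 of 100 drawn splits of the 10 libraries into 5 and 5 called at least the real 18 genes. These include the real one, and the highest other called 29. The other 9 part 1 pair only, where the real split parts all 5. With culture as a fixed effect, a split that parts 1 pair compares only the 2 libraries of that culture. Those 9 therefore repeat the contrasts of few cultures, and that count neither excludes chance nor points to it. The 64 that part 3 pairs called at most 4. Of the 16 assignments that part all pairs each of the others called 0, but with a smallest share of 0.0625 they are too few for a share under 0.05.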
